A study of Mus musculus with 3 samples.

How the data were processed

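The data are single-cell measurements of aortic cells from Ldlr-deficient mice, which lack the low-density lipoprotein receptor and become hypercholesterolaemic on a fatty diet. All mice received an antibody against CD8, so there was 1 treatment arm and no untreated control. The 3 deposited libraries (gene expression, surface protein tags and hashtags) were made from the same cells. Hashtags 6 to 10, antibody-borne barcodes added before pooling, each mark 1 pool of 2 aortas, so the 5 pools are the biological replicates.

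The deposited matrices hold raw UMI counts per barcode for genes, surface tags and hashtags, per the file headers. Reads were aligned to the mm10 mouse genome and counted with Cell Ranger, per the submitters' processing notes, and the matrix header gives version 3.1.0. The authors' own cell filtering and clustering in Seurat 3.0.0 are mentioned in those notes, and their cell calls were not used here. The protocol text that came with the labels stops before its end, and the antibody list is not given in the sources used here.

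The gene expression library held 51277858 UMIs over 6493 barcodes and 31053 genes, with 500 to 66626 UMIs per barcode and a median of 5811. The surface tag library held 9835044 tags over 42 antibodies and the hashtag library 3408648 tags. Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were removed, which left 5520 and took out 973. Hashtags were called with HTODemux in Seurat 5.3.0 at a positive quantile of 0.99. It called 810 barcodes (14.7%) positive for more than 1 hashtag, and these were removed as doublets, leaving 4710. Scrublet called 1 further barcode, a simulated-doublet score that did not separate here, so doublets within 1 pool remain in the data.

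To keep the counting error of the grouping out of the tests, each UMI was assigned at random, with probability 0.5, to a clustering matrix or to a held-out matrix. Clustering of the first used Scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9) and gave 30 clusters. A cluster took the name of its best-matching marker list, fixed before the data were examined, when at least 3 of the markers were up. A marker was up when detected in at least 15% of the cluster's cells and at least 1 log2 unit above the median cluster. Names carry "-like" because they rest on RNA markers alone. A cluster whose leading genes held more genes of another cell type than of its best match was left unnamed. Of the 5 unnamed clusters (931 cells), clusters 5 and 15 had under 3 markers, clusters 3 and 6 had fibroblast markers and cluster 17 T cell markers but led with genes of another type. The markers chose the classes, so marker genes are not independent evidence for a class. Nor are other genes that shaped the clusters, since both matrices come from the same cells. In the clustering matrix, Cd5l, Syngr1, Mmp12 and Gngt2 were among the leading genes of the foamy macrophage-like cluster, and Cd163 of the resident one. A difference of such genes in the held-out matrix was therefore to be foreseen.

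For each macrophage comparison, held-out UMIs were summed per pool and class, with at least 10 cells per sum, and fitted in edgeR 4.0.16 (TMM scaling, its default low-count filter, quasi-likelihood test) with the pool as a block. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05. Both classes of a comparison come from the same aortas, which pairs them by design. Checked on the data, the correlation of the paired deviations ran from -0.0390 to 0.0654 over the pools for foamy against inflammatory, from 0.109 to 0.389 for resident against inflammatory and from -0.00197 to 0.208 for foamy against resident. The p-values describe the spread between pools of treated mice and say nothing about an effect of the antibody. Surface tags were tested with limma 3.58.1 on log2 of tag CPM (counts scaled to the same total) plus 1, summed per pool and class, over all 42 antibodies. This scale is a share of all tags in a class, and no isotype control antibody was in the panel. Some tagged proteins are products of naming markers: TIM4 of the resident marker Timd4, CD11c and CD9 of the foamy markers Itgax and Cd9. Where those classes are compared, these proteins are not independent evidence for them.

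The fit was tested on simulated data drawn from the means and library sizes of each comparison, with 100 genes changed at each fold size between macrophage classes. Beyond the pool effect, the simulated spread was 1 fixed value for all comparisons. It lay below the coefficients of variation of 0.236, 0.232 and 0.188 fitted to the macrophage data, in the order given next. Recovery and wrong calls in the data may thus be worse than in the simulation. At a log2 fold change of 1 the fit recovered 57% of changed genes for foamy against inflammatory, 74% for resident against inflammatory and 92% for foamy against resident. At a log2 fold change of 2 it recovered 91%, 96% and 97%. Wrong calls made up 1.33%, 2.30% and 1.56% of all calls. For modulated against contractile and fibroblast-like cells, with 68 and 100 genes changed at each size, it recovered 86.8% and 57% at 1, 95.6% and 92% at 2, and 1.59% and 2.61% of calls were wrong. The same fixed spread was used there, although the real sums hold 1 to 8 smooth muscle-like cells. It was not set against the spread of those sums, so these rates may be too favourable.

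Lists of genes written before the data were examined, 23 in number, were tested with camera in limma at a preset correlation of 0.01 between genes, and also with the correlation estimated from the data and with fry. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The modulated and contractile smooth muscle classes had few cells with a hashtag (15 and 23), and no pool held the 10 of each that were asked for before the data were examined, so they and the fibroblast class they were set against were pooled over all barcodes and compared as ratios of held-out UMIs per class total (CPM), where the totals were taken after the low-count filter and scaled by TMM factors of the 2 classes compared. Those ratios have no replicates and no test. The edgeR fit on the pool sums of these few cells was added after the data were seen. The 95% Poisson intervals of the ratios cover counting error only, and the median of each list was set against 10000 random lists matched on expression. A gene with 0 UMIs in a class was given a bound against 3 counts over the class. Shares of cells carry 95% Clopper-Pearson intervals, which also cover counting error only, and the mean and SD over the 5 pools. To set CD8 detection on 1 depth, barcodes were also thinned to 2000 UMIs.

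Named genes followed a rule set before the data were examined: the 8 highest and the 8 lowest past the threshold with the same direction in every pool and at least 50 CPM in the higher class, leaving out the class markers. To these came up to 3 genes per list with the largest change past the threshold, or the member at the highest CPM where none passed. Where there was no test, a level of at least 50 CPM in either class took the place of the threshold. The genes Cd8a, Cd8b1, Cd4 and Ldlr were named in advance as the antibody target, its counterpart and the deleted gene. Gene positions are from the GENCODE annotation of mm10.

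The alternatives tried were DESeq2-type size factors, DESeq2 1.42.0 in place of edgeR, no low-count filter, no block, all UMIs in place of held-out ones, leaving out each pool, Leiden resolutions of 1.0 and 2.0, a mitochondrial limit of 5%, a minimum of 500 genes, a hashtag quantile of 0.999, the removal of the Scrublet call and a different random split of the UMIs. For surface tags, a centred log ratio and a pseudocount of 10 were tried. Chosen after the data were seen were fits without barcodes holding more than 20 UMIs of mesenchymal marker genes, fits on pools 1, 3 and 5 or on pools 2 and 4, tag gates of 5 and 20, and the smooth muscle comparisons without 1 cluster of cartilage-like cells. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9, and R 4.3.3, were used.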

Results

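Aortic cells were profiled from Ldlr-deficient mice fed a diet with 15% milk fat and 1.25% cholesterol for 13 weeks. During the last 4 weeks the mice received an antibody against CD8, a marker of cytotoxic T cells, at 100 µg in 2 doses per week. The stated purpose was to map all aortic cells after CD8+ T cell depletion. Viable cells were sorted without red cells and without leukocytes labelled by a 5-minute intravenous CD45 antibody, which marks cells in the bloodstream. Leukocytes were set to about 50% of the sorted cells, and 18000 cells were loaded. One library each of gene expression, surface protein tags and hashtags came from these cells, 10 aortas in 5 pools, with no untreated arm.

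After filtering, 4710 barcodes were grouped, and 2613 of them carried the hashtag of 1 pool. The other 2097 had no callable hashtag. Leukocyte classes made up 2328 barcodes (49.4%), a share set by the sort, and 1.20% of them lacked a hashtag. Stromal clusters other than endothelial, that is smooth muscle-like and fibroblast-like classes with the unnamed clusters 3 and 6, made up 2243 barcodes, of which 2023 (90.2%) lacked a hashtag. By class, 93.5% of contractile and 89.2% of modulated smooth muscle-like and 88.4% of fibroblast-like barcodes lacked one. The endothelial-like class lay between, with 33.1% lacking one. Pools 1 to 5 held 481, 363, 675, 546 and 548 cells with 3249032, 2818849, 4445050, 3994703 and 3411094 UMIs. The labels give the cell type as CD45+, whereas the protocol and the data include stromal cells.

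Among leukocytes with a pool, B cell-like cells were the class with the highest mean share, 20.3% ± 9.84 (SD, n = 5 pools). The T cell-like class made up 14.4% ± 5.17 and the gamma delta T cell-like class 6.96% ± 2.83, together 21.4% ± 3.50. Macrophage-like classes together reached 20.8% ± 3.47. They divided into resident 8.80% ± 3.11, inflammatory 7.03% ± 1.06 and foamy 4.94% ± 1.16, the last being macrophages with the RNA profile of lipid-laden cells. Trem2, a marker on the foamy list, was also among the leading genes of the inflammatory cluster, so that profile was not wholly particular to the foamy class. NK cell-like cells made up 7.89% ± 2.28 and dendritic cells of the cDC2-like class 6.40% ± 1.86. Monocyte-like cells made up 3.74% ± 1.69, neutrophil-like cells 3.90% ± 1.68 and mast cell-like cells 0.707% ± 0.489. B cell-like cells ranged from 7.72% to 35.0% of leukocytes between pools and ILC2-like cells from 0 to 8.04%. The latter range depends on the clusters. Pools 1 to 5 held 7, 25, 0, 32 and 2 ILC2-like cells, and 5, 3, 38, 7 and 40 cells of the unnamed cluster 15, whose leading genes included Il1rl1 and Gata3, also leading genes of the ILC2-like cluster. The macrophage share depended on the names. It was 11.2% at resolution 1.0, 10.7% with a 5% mitochondrial limit, 8.14% with a 500-gene minimum and 11.5% with another random split of UMIs, where most inflammatory macrophage-like cells stayed together but lost their name.

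**Figure D1:**
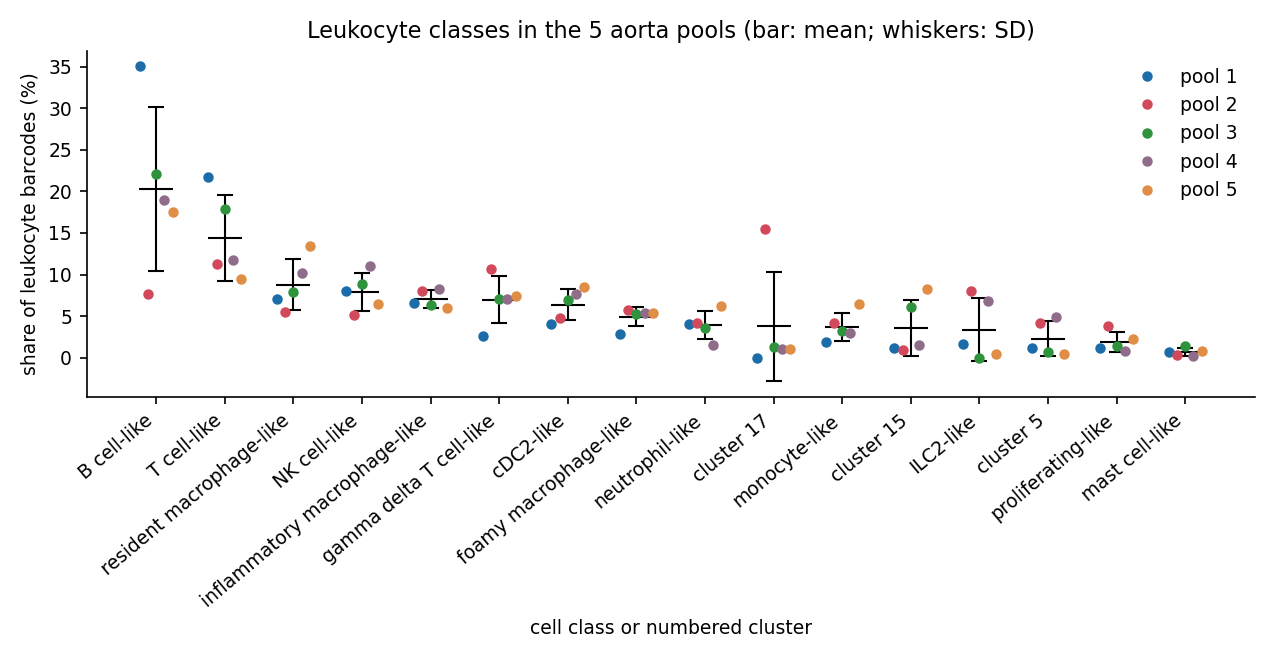
Share of each leukocyte class or unnamed cluster (percent of leukocytes with a pool, vertical axis), with 1 dot per pool and a bar with whiskers for the mean ± SD over 5 pools. B cell-like cells spread from 7.72% to 35.0%, while inflammatory macrophage-like cells stayed between 5.99% and 8.30%.

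Outside the leukocytes, all 2382 remaining barcodes were counted together because few had a pool. Fibroblast-like cells made up 42.9% of them (1023 cells, 95% interval 40.9% to 45.0%) and contractile smooth muscle-like cells 14.9% (356 cells, 13.5% to 16.4%). Modulated smooth muscle-like cells, which had less RNA of contractile genes than the contractile class, made up 5.84% (139 cells, 4.93% to 6.85%). Endothelial-like cells also numbered 139. Unnamed clusters held 30.4% (725 barcodes), all in clusters 3 and 6. Both carried fibroblast markers, 6 of 7 and 7 of 7, but cluster 3 (397 barcodes) was led by red-cell RNA and cluster 6 (328 barcodes) by genes that included Mpz of Schwann cells, so the fibroblast-like share leaves them out.

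The first comparison asked how many T cells with CD8 remained. No cluster had CD8 T cells as its best match, so no class carries that name. CD8 T cell was the next match, with 5 of its markers in the NK cell-like cluster, 4 each in the proliferating-like cluster and the unnamed cluster 17, and 2 each in the T cell-like clusters 4 and 24. At least 1 UMI of Cd8a or Cd8b1, the genes of the CD8 chains, was found in 64 of 494 cells of the T cell-like and gamma delta T cell-like classes (13.0%, 95% interval 10.1% to 16.2%), with a pool mean of 13.0% ± 4.48 (SD, n = 5). In the NK cell-like class, 66 of 187 cells had such a UMI (35.3%, 28.5% to 42.6%, pool mean 33.7% ± 8.75). All markers of the CD8 T cell list (Cd8a, Cd8b1, Cd3e, Trac and Gzmk) were up in this cluster, so it may hold CD8 T cells. The share in the T cell-like classes is therefore not a count of all CD8 T cells that remained. Among 41 proliferating-like cells, 14 had a Cd8a UMI and 15 a Cd8b1 UMI. In B cell-like cells, which do not make CD8, 3 of 480 had one (0.625%, 0.129% to 1.82%). With barcodes thinned to 2000 UMIs, the shares were 8.98% of T cell-like cells (6.57% to 11.9%), 29.8% of NK cell-like cells and 0 of 469 B cell-like cells (upper limit 0.783%).

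The surface protein gave similar shares. At least 10 CD8a tags were found on 52 of 494 T cell-like cells (10.5%, 7.96% to 13.6%, pool mean 10.0% ± 3.52). They were found on 65 of 187 NK cell-like cells (34.8%, 28.0% to 42.1%, pool mean 34.5% ± 5.04) and on 0 of 480 B cell-like cells (upper limit 0.766%). In the gamma delta T cell-like clusters, which are part of the 494, they were on 0 of 60 and 0 of 97 cells. At least 10 CD4 tags were found on 286 T cell-like cells (57.9%, 53.4% to 62.3%, pool mean 55.8% ± 14.0) and on 19 NK cell-like cells (10.2%). A Cd4 UMI was found in 148 of the T cell-like cells. Both tags were on 6 T cell-like cells (1.21%), and 4 had between 5 and 19 CD8a tags, so few cells were near the limit. With no untreated arm, the shares cannot be set against those without the antibody. Cd8a lies on chromosome 6 from 71373427 to 71379173 on the plus strand (mm10, ENSMUSG00000053977), Cd8b1 on chromosome 6 from 71322788 to 71337494 on the plus strand (ENSMUSG00000053044) and Cd4 on chromosome 6 from 124864692 to 124888221 on the minus strand (ENSMUSG00000023274).

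**Figure D2:**
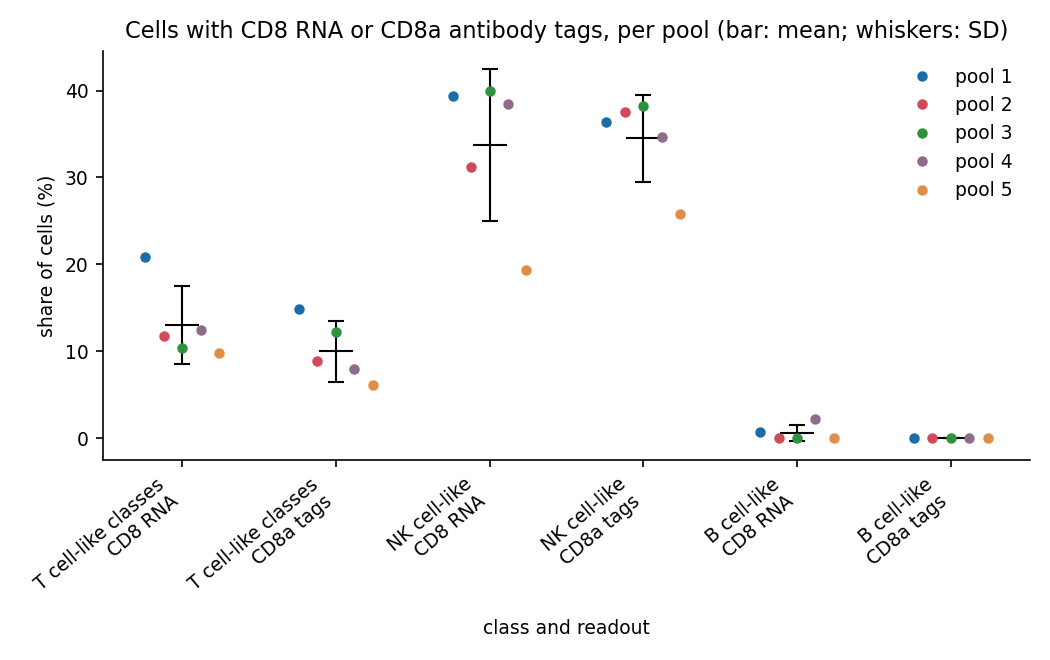
Share of cells with CD8 (percent, vertical axis) in T cell-like, NK cell-like and B cell-like cells, by Cd8a or Cd8b1 UMI and by at least 10 CD8a tags, with 1 dot per pool and a bar with whiskers for the mean ± SD over 5 pools. The NK cell-like class had the highest CD8a tag share at 34.5% on average, and no B cell-like cell reached 10 tags.

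Cd5l, a secreted scavenger-receptor protein (mm10 chromosome 3, 87357881 to 87371073, plus strand, ENSMUSG00000015854), was higher in foamy macrophage-like than in inflammatory macrophage-like cells by a log2 fold change of 8.35 ± 0.40 (SE, n = 5 pools, edgeR adjusted p = 9.67e-11). Its level was 3983 ± 2475 CPM against 11.1 ± 19.6 CPM (SD). Mfge8, which bridges dying cells to phagocytes, was higher by 6.52 ± 0.31 (adjusted p = 9.67e-11), the lysosomal protease gene Ctsl by 4.16 ± 0.21 (adjusted p = 1.19e-10) and Ctsd by 2.63 ± 0.32 (adjusted p = 1.61e-05). The lipid carrier gene Apoe rose by 1.66 ± 0.17 (adjusted p = 3.33e-06) and the metalloproteinase gene Mmp12 by 1.69 ± 0.29 (adjusted p = 0.000383). In the other direction, the chemokine gene Ccl2 fell by 3.08 (SE 0.48, adjusted p = 0.000183) and the MHC class II gene H2-Ab1 fell by 2.10 (SE 0.34, adjusted p = 0.000249). The heat-shock gene Hspa1b had a log2 fold change of -4.79 ± 0.52, and the nuclear RNA Xist one of -4.83 ± 0.44 (adjusted p = 5.41e-07). Each of these held its direction in 5 of 5 pools. The other highest genes were Il18bp, which binds interleukin 18, at 5.04 ± 0.64, Syngr1 at 3.92, Acp5 at 3.43, Tagln at 2.83 and S100a1 at 2.74. Among the lowest were Pid1 at -4.72, Hspa1a at -4.59, Lilrb4a at -4.35, Rgs1 at -4.19 and the integrin gene Itgam at -4.14. Mycbp2 had 0 UMIs in foamy cells against 152, which puts its log2 fold change at -2.34 or below, a bound against 3 counts over the class.

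By group, 8 of 18 lysosome genes were higher and none lower (9 adjusted over the list alone, list median 0.71, camera adjusted p = 0.0027, but adjusted p = 0.288 with an estimated correlation). All 13 immediate early genes, which respond within minutes to stimulation or tissue dissociation, were lower, Btg2 among them at -3.37 ± 0.52 (13 over the list alone, list median -2.13, camera adjusted p = 0.000641, but adjusted p = 0.560 with an estimated correlation). The classes also differed in RNA quality. Foamy barcodes had a median of 0.143% of UMIs from the nuclear RNAs Malat1, Neat1 and Xist against 2.62%, and a median depth of 1322.5 against 10799.5 UMIs. Red-cell RNA stood out in the foamy cells of pool 3 alone (6.93 above the mean of the pools on the log2 scale, against -2.15 to -1.31 in the others). All 6 mesenchymal marker genes were higher, including Mgp at 1.70 ± 0.34 (6 over the list alone, camera adjusted p = 2.80e-05, but adjusted p = 0.288 with an estimated correlation). Per barcode, the median number of UMIs of these markers was 4 in foamy and 5 in inflammatory cells, as in B cell-like (5) and T cell-like cells (4), at the depths given above. No background share was subtracted for these genes or for Tagln, Acta2 and Sparc. Of 3 matrix-degrading genes, Mmp12 and Timp2 (1.04 ± 0.28) were higher (2 over the list alone, camera adjusted p = 0.0331, but adjusted p = 0.560 with an estimated correlation and adjusted p = 0.0757 without the pool block). All 5 NF-kB targets tested were lower, with Nfkbia at -2.28 ± 0.41 in 4 of 5 pools (5 over the list alone). As a list they missed the threshold (camera adjusted p = 0.0614), though not without the pool block (adjusted p = 0.0362). MHC class II genes were lower in 6 of 8 and higher in 1 (7 over the list alone), and lipid genes higher in 4 of 9, such as Npc2 at 1.16 ± 0.19 and the lipase gene Lpl at 1.09 ± 0.29 (5 over the list alone). These lists had camera adjusted p of 0.125 and 0.0961. Efferocytosis genes went both ways (1 higher, 4 lower of 8, camera adjusted p = 0.574), with Axl at -3.76 ± 0.90. Interstitial matrix genes were higher in 3 of 4, with Sparc at 1.34 ± 0.35, and Fn1 was lower at -1.80 ± 0.49 (camera adjusted p = 0.0961). Without barcodes of more than 20 mesenchymal UMIs, the interstitial and lipid lists passed (camera adjusted p = 0.0149 and 0.0346, but adjusted p = 0.216 and 0.331 with an estimated correlation). No glycolysis gene of 6 passed, and the list median of 0.10 lay above the all-gene median of -0.19. Mitochondrial RNA was lower in 5 of 8 genes (6 over the list alone, list median -0.50, camera adjusted p = 0.299). The other 4 lists tested did not pass.

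In all, 350 of 1075 genes passed the threshold (121 higher and 229 lower in foamy cells), 298 of them by at least 1 on the log2 scale. The comparison used 114 foamy and 159 inflammatory cells, with 9321 to 276245 held-out UMIs per pool and class. The median log2 fold change of all genes was -0.19, and -0.34 with DESeq2-type size factors, so values close to these do not separate a gene from the scaling; every gene named here kept its direction under both. The count was 233 without pool 3, 223 without pool 4, 187 on pools 1, 3 and 5 against 382 on pools 2 and 4, 652 with all UMIs and 766 without the low-count filter (53 higher, 713 lower). Of 42 surface proteins, 3 passed in limma, all higher in foamy cells. The lysosomal proteins CD63 and CD68 had log2 fold changes of 4.46 ± 0.45 (adjusted p = 0.00208, 164 against 27.2 tags per cell) and 3.91 ± 0.64 (adjusted p = 0.0162, 15.4 against 4.20), and CD11c, an integrin of dendritic cells and macrophages, 2.50 ± 0.49 (adjusted p = 0.0265). CD11c is the product of Itgax, a naming marker of the foamy class. It passed as a share of all tags, as foamy barcodes held fewer tags in total (median 339 against 1705.5). Per cell there were 6476 tags over 114 foamy cells against 8273 over 159. The surface count was 1 without pool 3, 1 without pool 4, 5 without pool 5, 7 with the centred log ratio, 7 with a pseudocount of 10 and 10 without the pool block.

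Resident macrophage-like cells are a class defined by genes of long-lived tissue macrophages, and were also set against inflammatory ones. Spp1, which encodes osteopontin (mm10 chromosome 5, 104435118 to 104441050, plus strand, ENSMUSG00000029304), fell by 5.84 (log2, SE 0.43, n = 5 pools, edgeR adjusted p = 3.47e-06). Mmp12 had a log2 fold change of -5.03 ± 0.44 and the lectin gene Lgals3, a marker of activated and foamy macrophages, one of -3.01 ± 0.37. Cd163, the haptoglobin-haemoglobin receptor gene, was higher by 3.15 ± 0.57 (adjusted p = 0.00171) and the growth-arrest gene Gas6, a ligand for clearance of dying cells, by 2.90 ± 0.34 (adjusted p = 5.73e-05). Other genes lower in resident cells were Nes at -4.09, AA467197 at -4.08, Lat2 at -2.98, Glipr1 at -2.93 and Cd72 at -2.67 ± 0.27 (adjusted p = 2.32e-05). All of these pointed the same way in 5 of 5 pools.

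The 8 highest genes were of mesenchymal kind, led by Pcolce, a collagen-processing factor, at 5.46 ± 0.42 (adjusted p = 4.26e-06), Cygb at 5.16, Mgp at 4.91 ± 0.29 (adjusted p = 1.05e-06), Bicc1 at 4.83, Lum at 4.62, Aebp1 at 4.60, Col1a1 at 4.42 and, just below it, Col1a2. Of 231 resident macrophage-like barcodes, 37 held more than 20 UMIs of mesenchymal markers. Without such barcodes only Mgp and Col1a2 of the 8 were still tested, at 1.70 and 1.66, and both stayed past the threshold. Of the 8 lowest, 7 were tested and stayed past it (-5.67 to -2.36). The count of genes then was 173 (87 higher, 86 lower), of which 145 were among those found with all barcodes.

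With all barcodes, 362 of 2162 genes passed (196 higher, 166 lower), 265 by at least 1 on the log2 scale. The test covered 208 resident and 159 inflammatory cells, with 24956 to 276245 held-out UMIs. The count was 693 with all UMIs and 992 without the low-count filter, and 399 on pools 1, 3 and 5 against 279 on pools 2 and 4. Interstitial matrix genes were higher in 11 of 12 (11 over the list alone, median 4.00, camera adjusted p = 4.15e-11, but adjusted p = 0.272 with an estimated correlation) and mesenchymal markers in 6 of 6 (6 over the list alone, camera adjusted p = 5.75e-09, but adjusted p = 0.272 with an estimated correlation). Without the mesenchymal barcodes the interstitial list had 3 higher and 1 lower of 4 (camera adjusted p = 0.0339, but adjusted p = 0.435 with an estimated correlation). The mesenchymal markers were then still higher in 4 of 4 (median 1.85, camera adjusted p = 9.22e-05, but adjusted p = 0.435 with an estimated correlation). The resident barcodes left held a median of 5 mesenchymal UMIs, as did all inflammatory ones, at median depths of 1519 and 10799.5 UMIs. An equal count is a larger share of a shallower barcode, and no background share was subtracted. Complement and stromal chemokine genes, among them C3 at 3.75 ± 0.35 and C1s1 at 3.84 ± 0.41, were higher in 7 of 11 and lower in 1 (8 over the list alone, camera adjusted p = 0.000226, but adjusted p = 0.390 with an estimated correlation). Without those barcodes, 3 of 7 were higher and 1 lower (camera adjusted p = 0.0931). Immediate early genes such as Egr1 (1.88 ± 0.30), Nr4a1 (1.56 ± 0.28) and Jun (1.55 ± 0.27) were higher in 8 of 16 (12 over the list alone, camera adjusted p = 0.000226, but adjusted p = 0.390 with an estimated correlation). Without mesenchymal barcodes 4 of 16 were higher (list median 0.24, camera adjusted p = 0.0421, but adjusted p = 0.648 with an estimated correlation).

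Leukocyte markers were lower in 6 of 9, Cd52 among them at -1.33 ± 0.20 (7 over the list alone, camera adjusted p = 0.000992, but adjusted p = 0.390 with an estimated correlation), and in 2 of 9 without mesenchymal barcodes (camera adjusted p = 0.163). Glycolysis genes were lower in 3 of 8, with Gapdh at -1.23 ± 0.22 (5 over the list alone, camera adjusted p = 0.00806, but adjusted p = 0.390 with an estimated correlation). Cell cycle genes were lower in 2 of 3 (3 over the list alone, camera adjusted p = 0.0489, but adjusted p = 0.531 with an estimated correlation), and in 0 of 3 without mesenchymal barcodes (camera adjusted p = 0.207). Lysosome genes such as Cd68 (-1.47 ± 0.24) and Hexb (-1.42 ± 0.25) were lower in 4 of 18 and higher in 1 (6 over the list alone, camera adjusted p = 0.0598, 0.0260 without the pool block, 0.0339 without mesenchymal barcodes and adjusted p = 0.818 with an estimated correlation). Lipid genes were lower in 4 of 12 and higher in 1 (9 over the list alone, list median -0.33, camera adjusted p = 0.348), with the cholesterol exporter gene Abcg1 at -2.12 ± 0.44. Without mesenchymal barcodes they turned to 3 higher and 1 lower of 11 (list median 0.42, camera adjusted p = 0.828). Of the NF-kB targets 1 was higher and 3 lower of 14 (5 over the list alone, camera adjusted p = 0.878), with the scavenger chemokine gene Cxcl16 at -1.82 ± 0.24. The other 7 lists tested did not pass. Of 42 surface proteins, 3 passed in limma. The tetraspanin CD9 was lower on resident cells (-2.77 ± 0.45, adjusted p = 0.0095, 32.0 against 266 tags per cell). The resident-macrophage protein TIM4 was higher (2.71 ± 0.54, adjusted p = 0.0175, 60.5 against 18.3), as was CD163 (2.70 ± 0.61, adjusted p = 0.0257, 869 against 273). TIM4 is the product of Timd4, a naming marker of the resident class, so its difference is not independent of the name. Without pool 3 or without pool 5 none of the 42 passed in limma (8 and 6 did before adjustment), 1 passed without pool 1, and 5 without the pool block.

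Foamy cells set against resident ones again had more Cd5l, by a log2 fold change of 6.99 ± 0.28 (SE, n = 5 pools, edgeR adjusted p = 3.4e-10). Lgals3 rose by 4.38 ± 0.21 (adjusted p = 7.98e-10), Mfge8 by 4.42 ± 0.36, Ctsd by 3.32 ± 0.17, Ctsl by 3.02 ± 0.25 and Cd68 by 2.09 ± 0.26. Gngt2, at 4.00, Pld3, and S100a1, at 2.82, were also among the highest. Lower in foamy cells were the heat-shock genes Hspa1b at -5.66 ± 0.42 (adjusted p = 6.89e-08) and Hspa1a at -5.54 ± 0.40, the transcription factor gene Maf at -5.34 ± 0.57, Xist at -5.05 ± 0.48, Jun at -4.40 ± 0.32, the nuclear RNA Malat1 at -4.32 ± 0.26 (adjusted p = 1.06e-08), Cfh at -4.09 ± 0.39 and Pf4 at -4.02 ± 0.46. All held in 5 of 5 pools. Without mesenchymal barcodes the 8 highest stayed past the threshold (3.11 to 6.37), as did Maf, Malat1, Cfh and Pf4 of the lowest (-5.60 to -3.04), while Hspa1b, Hspa1a, Xist and Jun were no longer tested.

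Lysosome genes were higher in 8 of 12 (9 over the list alone, median 1.63, camera adjusted p = 0.000637, but adjusted p = 0.215 with an estimated correlation), and lipid genes in 3 of 4, namely Lpl (1.87 ± 0.37), Npc2 (1.52 ± 0.21) and Apoe (0.98 ± 0.19) (3 over the list alone, camera adjusted p = 0.0596). Immediate early genes were lower in 10 of 10 (10 over the list alone, median -3.41, camera adjusted p = 0.000287, but adjusted p = 0.270 with an estimated correlation), and in 6 of 6 without mesenchymal barcodes (median -2.05, camera adjusted p = 0.0440, but adjusted p = 0.520 with an estimated correlation). Mitochondrial RNA was lower in 8 of 8, mt-Nd2 at -1.22 ± 0.20 (8 over the list alone, camera adjusted p = 0.0184, but adjusted p = 0.398 with an estimated correlation). Leukocyte markers, Tyrobp among them at 1.48 ± 0.17, were higher in 4 of 5 (4 over the list alone, camera adjusted p = 0.0291, but adjusted p = 0.215 with an estimated correlation). Without mesenchymal barcodes they were higher in 3 of 6 and lower in 1 (camera adjusted p = 0.269). The mesenchymal markers were lower in 6 of 6, with Mgp at -3.55 ± 0.19 (6 over the list alone, camera adjusted p = 0.00104, but adjusted p = 0.215 with an estimated correlation). The interstitial genes were lower in 7 of 7, with Col1a1 at -3.86 ± 0.53 (7 over the list alone, camera adjusted p = 0.00121, but adjusted p = 0.307 with an estimated correlation). The complement and stromal chemokine genes were lower in 3 of 3, with C3 at -3.05 ± 0.43 (3 over the list alone, camera adjusted p = 0.0319, but adjusted p = 0.215 with an estimated correlation). Once mesenchymal barcodes were removed, fewer than 3 members of each of these last lists were still tested. Of the mesenchymal and interstitial genes only Mgp and Dcn remained, and neither passed (-0.12, adjusted p = 0.788, and 0.25, adjusted p = 0.496). Of the complement genes C4b and Cfh remained, and both were lower (-3.54 and -3.04). Dcn and C4b were chosen after their values were seen. MHC class II genes were lower in 4 of 5 and higher in 1 (5 over the list alone, camera adjusted p = 0.343), with H2-Ab1 at -2.18 ± 0.24. The other 2 lists tested did not pass.

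The threshold was passed by 181 of 333 genes (81 higher and 100 lower in foamy cells), 131 by at least 1 on the log2 scale, with 114 foamy and 208 resident cells and 9321 to 140109 held-out UMIs. The count was 323 without pool 2, 282 on pools 1, 3 and 5 against 178 on pools 2 and 4, 329 at the stricter hashtag quantile and 85 with a 5% mitochondrial limit. It was 423 with all UMIs and 956 without the low-count filter (91 higher, 865 lower). Against resident cells too, foamy barcodes held less nuclear RNA (median 0.143% against 2.29% of UMIs) and were shallower (median 1322.5 against 1691 UMIs). Of 42 surface proteins, 11 passed in limma, and 18 with the centred log ratio. As a share of all tags CD11c (4.55 ± 0.50, adjusted p = 0.000748, 56.8 against 9.30 tags per cell), CD63 (4.29 ± 0.36, adjusted p = 0.000401, 164 against 27.0 per cell), CD68 (3.68 ± 0.40, 15.4 against 3.77 per cell), CD9 (3.28 ± 0.27, adjusted p = 0.000401, 81.9 against 32.0 per cell) and the checkpoint ligand CD274 (2.68, 3.56 against 2.73 per cell) were higher on foamy cells, and CD163 (-3.64 ± 0.35, adjusted p = 0.000558, 16.9 against 869 per cell) was lower. CD11c and CD9 are products of naming markers of the foamy class, so their differences are not independent of the name. CD4 (1.64), FCeRIa (1.62), ICAM1 (1.58), Ly6C (1.41) and Ly6G (0.97) were higher as a share of all tags but not per cell. ICAM1 had 14.6 tags per foamy cell against 17.4.

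**Figure D3:**
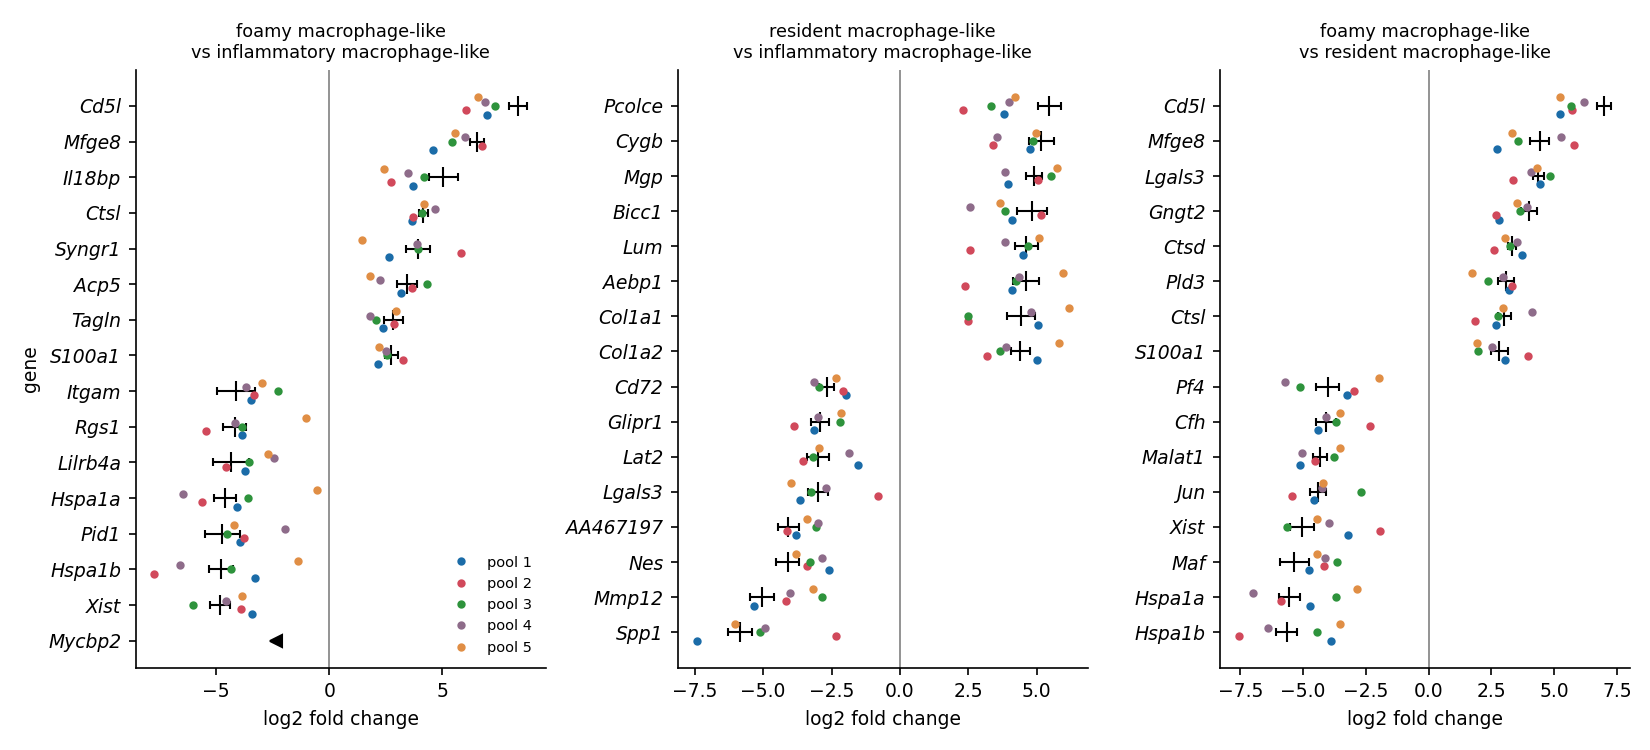
Differences between macrophage classes for named genes (log2, horizontal axis), with 1 dot per pool (log2 CPM with a prior count of 2, which draws low genes toward 0) a tick with whisker for the fitted log2 fold change ± SE, and a triangle alone for the bound of Mycbp2. The fitted change of Cd5l was 8.35 for foamy against inflammatory cells and 6.99 for foamy against resident cells.

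Modulated smooth muscle-like cells (139 barcodes) were next compared with contractile ones (356). Whether 1 class arose from the other was not tested, as no lineage was traced. The ratios of this comparison pool all barcodes and have no replicates, since only 15 and 23 of the barcodes carried a pool. An edgeR fit with the pool as a block on those few barcodes was added after the data were seen. Contractile genes were lower, such as Kcnmb1, a channel subunit of smooth muscle, with a log2 ratio of -6.37 (95% Poisson interval -9.42 to -4.51, 2 against 299 UMIs). Rgs5, a regulator of vascular tone signals (mm10 chromosome 1, 169655501 to 169695813, plus strand, ENSMUSG00000026678), had one of -7.40 (-8.24 to -6.68, 15 against 4585 UMIs). Rgs5 was on the pericyte marker list and not on the contractile list. Spp1 was higher at 6.79 (6.48 to 7.12), from 42.7 to 4735 CPM. The matrix genes Dcn, at 3.60 (3.53 to 3.67), and Lum, at 3.32 (3.20 to 3.44), were higher too, as was complement C3 at 3.30 (3.09 to 3.51). Ccl2 was at 3.40 (3.05 to 3.77), Timp1 at 3.59 (3.33 to 3.85) and Mmp2 at 3.54 (3.25 to 3.85). At resolution 1.0, where the name modulated went to 16 cartilage-like cells alone, Ccl2 reversed to -1.06. Ptprz1, at -8.06 (-13.37 to -5.57, 1 against 482 UMIs), and Actg2, at -7.43 (1 against 311 UMIs), were among the lowest. The cartilage collagen gene Col2a1 had the highest ratio, 9.61 (8.63 to 10.82, 3457 against 8 UMIs).

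The class joins 2 clusters, 1 of 123 cells and 1 of 16 cartilage-like cells. The cluster of 123 had 7 of 9 modulated smooth muscle markers up, and its next match was fibroblast, with 6 markers up. The contractile class joins cluster 21 (275 cells, median 12622 UMIs) and cluster 27 (81 cells, median 1809 UMIs). The next match of both was pericyte, with 3 and 2 markers up, so a difference in pericyte genes such as Rgs5 cannot be told from one in contractile state. Without the cartilage-like cluster, Col2a1 was at 2.00 (0.69 to 3.44) and Spp1 at 6.14 (5.82 to 6.47), and Col10a1, at 8.66 with both, could not be measured. Ldlr, the deleted gene, had 14, 11 and 38 held-out UMIs in modulated, contractile and fibroblast-like cells, and its intervals in both comparisons included 0 (-0.04 to 2.48 and -0.03 to 1.88).

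By group, all 20 contractile apparatus genes lay below 0 with their intervals (median -3.89), and no random list of 10000 had so low a median. The list median was -3.11 at resolution 1.0 and -3.41 with a 5% mitochondrial limit. Of 19 cartilage and bone genes 18 lay above 0 (median 4.31, and 1.40 without the cartilage-like cluster). Medians above those of all random lists were also found for interstitial matrix (1.25, 17 of 24 above), matrix-degrading genes (2.00, 10 of 13), complement and stromal chemokines (2.24, 16 of 17) and interferon-response genes (1.31, 10 of 15). Lipid genes were higher in 7 of 11 (median 1.28, percentile 99.99). MHC class I genes were higher in 9 of 10 (median 0.74, percentile 99.5), and H2-T23 had a ratio of 3.12 (2.64 to 3.63). H2-T23 reversed to -0.999 at resolution 1.0 and to -0.84 with a 5% mitochondrial limit. MHC class II genes were lower in 4 of 6 (median -0.82, percentile 1.97). Mitochondrial RNA lay below 0 in 8 of 8 genes (median -0.84, percentile 1.05), mt-Nd2 at -1.23 (-1.30 to -1.16). Lysosome genes were higher in 12 of 18 and lower in none (median 0.46, percentile 99.6), and NF-kB targets higher in 9 and lower in 4 of 16 (median 0.56, percentile 99.8). Immediate early genes, such as Atf3 at -1.45 (-1.63 to -1.27), went both ways (6 above and 10 below of 16, median -0.22, percentile 26.3). Cholesterol synthesis genes stayed within the random lists (median 0.17, percentile 72.3), as did basement membrane genes (median -0.15, percentile 30.6), although Lama5 was at -4.42 (-6.72 to -2.84, 3 against 116 UMIs).

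Against fibroblast-like cells (1023), modulated cells had more Spp1, by 8.26 (7.96 to 8.58, 5094 against 88 UMIs), and 7.61 (7.30 to 7.93) without the cartilage-like cluster. The contractile genes Csrp1, at 1.17 (0.87 to 1.47), and Actn1, at 1.08 (0.83 to 1.33), were higher, as was Timp1 at 1.99 (1.86 to 2.11). At resolution 1.0, Csrp1 was at -0.0885 and Actn1 at -0.74, and with a 5% mitochondrial limit Actn1 was at -0.40. The eotaxin gene Ccl11 was lower at -6.00 (-7.63 to -4.78, 5 against 1700 UMIs), as were the growth factor carrier gene Igfbp3 at -7.03 (-12.34 to -4.55, 1 against 696 UMIs), Inmt at -5.67 (-6.80 to -4.74), Gpc3 at -4.73 (-5.48 to -4.06), Il6 at -2.02 (-2.33 to -1.72), Lpl at -2.08 (-2.36 to -1.82) and Apoe at -1.73 (-1.82 to -1.64). The antibody genes Igkc, at -6.12 (-7.44 to -5.08, 7 against 2592 UMIs), and Jchain, at -5.62 (2 against 521 UMIs), are products of B cells and plasma cells. Col2a1 was higher by 9.36 (8.82 to 9.95), and by 1.75 (0.76 to 2.68) without the cartilage-like cluster.

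In this comparison 10 of 16 contractile apparatus genes were higher and none lower (median 0.55, above all random lists). The median turned negative where the name went mainly to the cartilage-like cells, at -0.57 for resolution 1.0 and at -0.24 for a 5% mitochondrial limit. Cartilage and bone genes were higher in 17 of 20 (median 4.90, and 1.06 without the cartilage-like cluster). Complement and stromal chemokine genes were lower in 13 of 17 and higher in 4 (median -1.11), NF-kB targets lower in 13 of 17 and higher in 2, and interferon-response genes lower in 11 of 20 and higher in 1 (median -0.72), and each of these medians lay below all random lists. MHC class II genes were lower in 5 of 8 (median -1.34, percentile 0.01), with Cd74 at -2.15 (-2.66 to -1.69). Lipid genes were lower in 5 of 16 (median -0.67, percentile 0.08), and immediate early genes in 16 of 16 (median -0.62, percentile 0.18), with Fosb at -1.35 (-1.47 to -1.23). Cholesterol synthesis genes (4 higher and 1 lower of 16, median 0.46, percentile 99.7) and glycolysis genes (7 higher and 2 lower of 14, median 0.40, percentile 99.9) had medians high among random lists. Interstitial matrix genes went both ways (8 higher and 11 lower of 24, median -0.01, percentile 86.0).

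Per pool, the sums held 1 to 8 modulated, 1 to 8 contractile and 17 to 32 fibroblast-like cells, and 7 of the 8 modulated cells of pool 3 were of the cartilage-like cluster. Against contractile cells 47 of 275 genes passed in edgeR (16 higher, 31 lower), with Myh11 at -7.78 ± 0.68 (SE, n = 5 pools, adjusted p = 0.000437), mt-Nd2 at -1.24 ± 0.17, Dcn at 5.07 ± 0.96 and Lum at 3.80 ± 0.77. Myh11 was a marker that named the contractile class, so its difference followed from the naming and is not independent evidence. Contractile apparatus genes were lower in 10 of 10 (list median -3.47, camera adjusted p = 3.91e-09, but adjusted p = 0.188 with an estimated correlation). Against fibroblast-like cells 24 of 1094 passed (4 higher, 20 lower, but 51 genes without the pool block and 67 in DESeq2), with Sfrp2 at -7.57 ± 0.68, Ccl11 at -7.06, Gpc3 at -5.29 ± 0.68 and Il6 at -3.77 ± 0.67. Of the contractile apparatus genes 3 were tested there and none passed (list median 0.32, camera adjusted p = 0.192). Of the cartilage and bone list only Mgp (0.83, adjusted p = 0.101) and Fmod (-1.52, adjusted p = 0.618) could be tested, and their median was -0.35. Spp1 and Col2a1 had too few counts to be tested in either fit. All genes past the threshold had the sign of the ratios over all barcodes. Those ratios include the same UMIs of these cells, so the match in sign is not independent evidence.

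Of the surface proteins, ICAM1, an adhesion molecule, had 40.2 tags per modulated cell against 10.3 on contractile and 20.2 on fibroblast-like cells. CD26 had 0.928, 0.626 and 4.10 tags per cell, and CD9 13.9, 24.0 and 10.2. These protein values were chosen after they were seen.

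**Figure D4:**
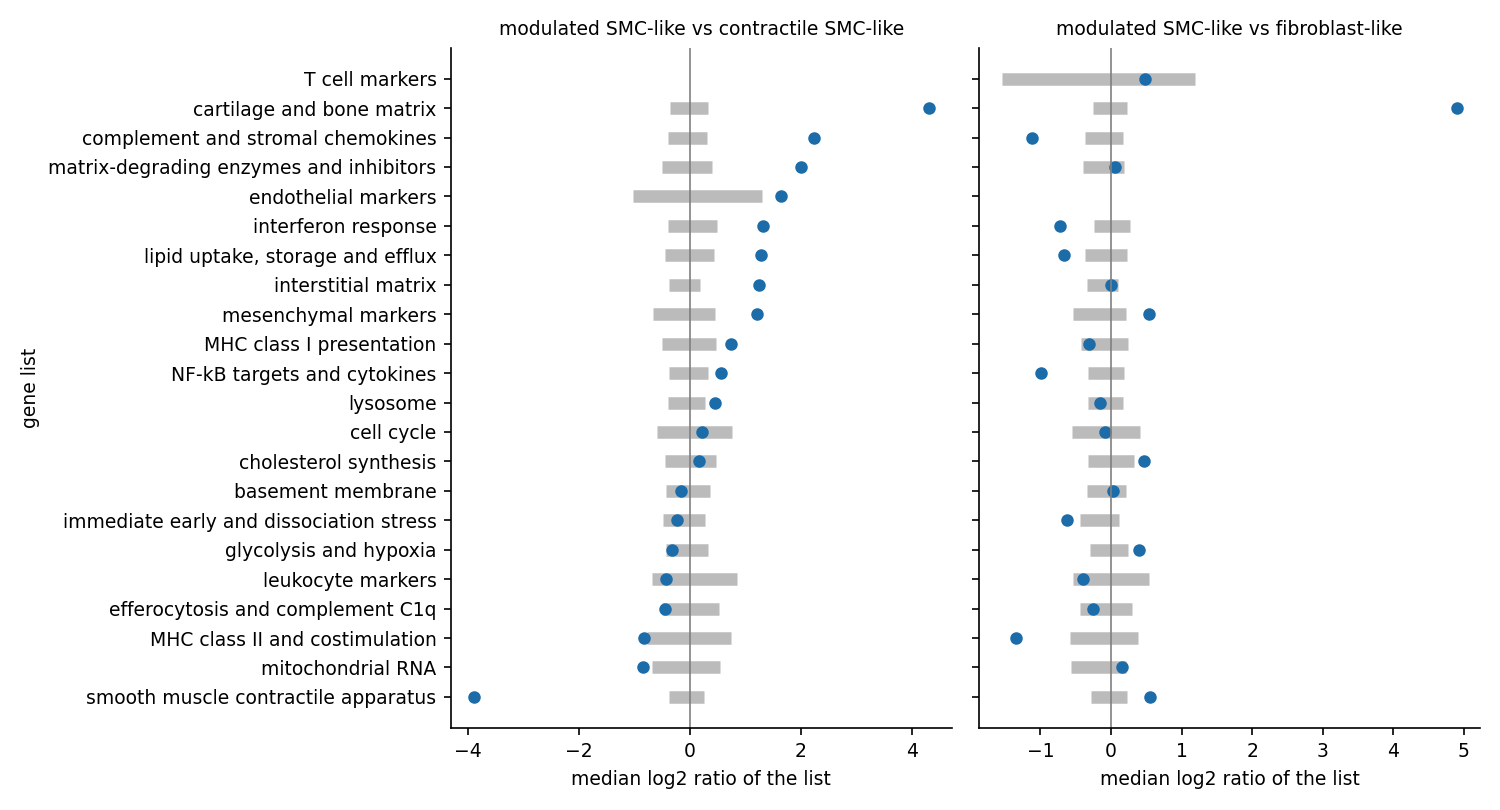
Median log2 ratio of each gene list (horizontal axis) in modulated against contractile smooth muscle-like cells and against fibroblast-like cells, with blue marks for list medians and grey bars for the central 95% of the medians of 10000 random lists matched on expression. The contractile list lies at -3.89 in the former and at 0.55 in the latter.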

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

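Chosen only after the result was seen were the tests of free RNA, of low UMI count, of dying cells that kept mitochondria, of doublets of a CD4 and a CD8 T cell, and the fits without barcodes of high mesenchymal RNA.

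Among 155 values measured in 5 pools, 7 had 1 pool standing apart from the other pools by Dixon's criterion, whereas chance alone gives about 5% of them, so such a number calls for no cause. The foamy macrophage-like share was lowest in pool 1, at 2.90% of leukocytes. The share of T cell-like cells with a Cd8a or Cd8b1 UMI was highest in pool 1, at 20.8%. The share of NK cell-like cells with CD8a tags was lowest in pool 5, at 25.8%, and none of the NK cell-like cells of pool 1 (0%) had CD4 tags. The log2 difference of Npc2 between foamy and inflammatory cells stood apart in pool 5, at 0.89, and that of Ctsz between resident and inflammatory cells in pool 2, at -0.78. The unnamed cluster 17 made up 15.4% of the leukocytes of pool 2. In data outside the comparisons, hashtag 2, which marks no pool, had 864 tags, against 1045 for all 5 unused hashtags and 3407603 for the 5 in use.

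Cluster 17 held 66 cells, 48 of them in pool 2, and was led by Rag1, the recombinase gene of developing lymphocytes, at 1346 CPM against 0 in T cell-like cells. A merging of a CD4 and a CD8 T cell in each droplet is argued against by a median of 3133 UMIs, below the 5920 of T cell-like cells, since doublets hold more RNA. Thymocytes carried over with the tissue remain a candidate explanation: 5 of 7 thymocyte genes listed beforehand exceeded T cell-like cells by more than 2 times with their intervals, among them Cd24a (692 against 14.7), Ly6d (539 against 6.58) and Themis (341 against 88.0). Of the 66 cells, 65 carried both CD4 and CD8a tags, and the sort gates, red-cell marker and intravenous CD45, would not remove thymocytes. Why pool 2 held most of them stays open, and no biological explanation was tested.

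Some resident macrophage-like barcodes carried mesenchymal RNA, 37 of 231 (16.02%, 95% interval 11.5% to 21.4%) holding more than 20 such UMIs. For these 37 barcodes, free RNA in the droplets is argued against because it would enter all droplets alike, yet 6 of 481 B cell-like barcodes (1.25%, 0.459% to 2.70%) exceeded the limit. A fibroblast in the same droplet is consistent with fibroblast markers in 33 of the 37 (89.2%, 74.6% to 97.0%), against 7 of the other 194 (3.61%), and with a median of 13656 UMIs against 1519. Macrophages that make these genes themselves, or hold fragments of eaten cells, stay open, and no biological explanation was tested. Without these barcodes 173 genes passed between resident and inflammatory cells, in place of 362. Mesenchymal markers were then still higher in 4 of 4 (median 1.85, camera adjusted p = 9.22e-05, but adjusted p = 0.435 with an estimated correlation). So the 37 barcodes do not carry the whole difference. The other 194 held a median of 5 mesenchymal UMIs, as did B cell-like barcodes (5), and no background share was subtracted. Inflammatory barcodes also held a median of 5, at a median depth of 10799.5 UMIs against 1519 in the 194. The limit of 20 cannot detect so low a background, so free RNA stays open for the 194.

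Foamy macrophage-like barcodes held little nuclear RNA, a median of 0.143% of UMIs from Malat1, Neat1 and Xist against 2.29% in resident cells. Low UMI count as the cause is argued against by the other 4 shallow leukocyte clusters, whose lowest median was 2.29%. Dying cells that lost cytoplasmic RNA and kept mitochondria are argued against by a median mitochondrial share of 1.92%, below the 2.74% and 3.12% of the other macrophage classes. Loss of the nucleus, as in cell fragments or cells broken during isolation, may account for it: 6 other nuclear RNAs listed beforehand had a ratio of 0.124 (0.0400 to 0.292, 5 UMIs against 407) to inflammatory cells. That ratio rests mainly on 1 gene, Kcnq1ot1, with 2 of the 5 and 304 of the 407 UMIs, and Miat had 0 in both classes. It stays open whether the low nuclear RNA arose in the plaque or in the preparation, and no biological explanation was tested.

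In each comparison of macrophage classes, the real split was the 1 with the most genes among 100 splits of the pool sums. For foamy against inflammatory cells it gave 350 genes and the highest other split 138, for resident against inflammatory 362 and 2, and for foamy against resident 181 and 0. Of the 100 splits, 14 parted the classes of every pool like the real one, and the highest of the others among these gave 0 genes. In the fits on pool sums of smooth muscle cells the real split was also the highest of 100, with 47 genes against contractile cells and the highest other at 22, and 24 against fibroblast-like cells and the highest other at 3. Those splits were not limited to ones that part the classes within each pool. All these classes were made by clustering on RNA, so splits that mix them were bound to give fewer genes. The rank of the real split therefore cannot exclude chance.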

How the results depend on the processing

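Chosen only after the data were seen were the tests on pools 1, 3 and 5 or 2 and 4, without mesenchymal barcodes, at tag gates of 5 and 20, with seed-2 clusters matched by cells and without the cartilage-like cluster, the pool sums of smooth muscle cells, and the DESeq2 fit of tagged T cells.

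Between foamy and inflammatory cells, 11 of 16 alternative counts stayed within 1.5 times of 350. The count was 766 (261 shared) without the low-count filter, 652 (327 shared) with all UMIs and 187 (167 shared) on pools 1, 3 and 5. Leaving out 1 pool gave 223 to 410, with 233 without pool 3 and 223 without pool 4. Between resident and inflammatory cells, 13 of 16 stayed, against 992 without the filter, 693 with all UMIs and 173 without mesenchymal barcodes (145 shared). Leaving out 1 pool gave 279 to 428. Between foamy and resident cells, 12 of 18 stayed, against 956 without the filter, 423 with all UMIs, 282 on pools 1, 3 and 5, 329 at the stricter hashtag quantile and 85 with at most 5% mitochondrial UMIs (79 shared). Leaving out 1 pool gave 150 to 323, the latter without pool 2. All UMIs hold more counts, and they also shaped the clusters. The causes of the other changes were not tested. Of the named genes' values, 48 of 645, 35 of 640 and 5 of 584 lost the threshold in these comparisons, and none reversed.

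Without the replicate block, the gene counts were 369, 284 and 180, and the block moved no macrophage gene count past 1.5 times. It changed surface counts, 10 and 5 without it in place of 3 and 3, and calls of single lists already given. Surface counts for foamy against inflammatory cells were 7 with the centred log ratio, 7 with a pseudocount of 10, and 1 to 5 on leaving out a pool (1 without pool 3, 1 without pool 4, 5 without pool 5). For resident against inflammatory cells they were 0 to 4 on leaving out a pool, in limma 0 without pool 3 and 0 without pool 5 (8 and 6 before adjustment) and 1 without pool 1. For foamy against resident cells they were 18 with the centred log ratio and 8 to 11 on leaving out a pool. Of the gene lists, 4 of 15, 7 of 17 and 7 of 11 passed in camera. With an estimated correlation 0, 0 and 0 did (2, 2 and 0 before adjustment), and with fry 7, 6 and 9.

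The inflammatory name was lost at resolution 1.0, a 5% mitochondrial limit, 500 genes and seed 2, and in 117 of 160 cells at resolution 2.0, so its comparisons gave no value there. Foamy against resident gave none at 500 genes, nor at resolution 1.0, where 169 of 231 resident macrophage-like cells fell in a cluster named foamy and none kept their name. The surface comparisons with inflammatory cells gave none at either resolution, nor did foamy against resident at 1.0. The macrophage share was 11.2% at resolution 1.0, 15.4% at 2.0, 10.7% with the 5% limit, 8.14% with 500 genes and 11.5% at seed 2. The T cell-like share was 25.1% with the 5% limit. Leaving out 1 pool gave 20.5% to 22.5% for T cell-like and 19.8% to 21.9% for macrophage-like classes. All 30 alternative values of CD8 detection lay within 1 SD over the pools, with 11.1% to 13.8% by UMI and 8.78% to 10.97% by tag on leaving out a pool. The latter could not fall outside, as leaving out 1 of 5 pools cannot move their mean by 1 SD.

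For the smooth muscle comparisons, the edgeR fit with a replicate block on pool sums below the set minimum of 10 cells gave 47 of 275 genes against contractile cells (57 without the block, 54 in DESeq2) and 24 of 1094 against fibroblast-like cells (51 and 67). The contractile list was at -3.47 against contractile cells and the cartilage list, then Mgp and Fmod alone, reversed to -0.35 against fibroblast-like cells. The name modulated went to 16 cartilage-like cells alone at resolution 1.0 and to 12 cells, 9 of them cartilage-like, with the 5% limit. Against contractile cells the contractile list was then at -3.11 and -3.41, and against fibroblast-like cells it reversed to -0.57 and -0.24. The cartilage list against fibroblast-like cells was at 5.97 at resolution 1.0, 3.20 with the Scrublet call removed and 1.06 without the cartilage-like cluster. At resolution 1.0, Ccl2 (-1.06) and H2-T23 (-0.999) reversed against contractile cells, and Csrp1 (-0.0885) and Actn1 (-0.74) against fibroblast-like cells. With the 5% limit, Optc (0.35), Ldb3 (0.67) and H2-T23 (-0.84) reversed against contractile cells and Actn1 (-0.40) against fibroblast-like cells. Of the other named genes' values, 85 of 356 and 117 of 347 moved beyond their interval. The added comparison of tagged T cells gave 192 genes in DESeq2 against 289 in edgeR. Fewer genes had enough counts to be tested in the foamy comparisons (1075 and 333, median 1322.5 UMIs per foamy barcode) than between resident and inflammatory cells (2162).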

Other observations

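The comparison of tagged T cells and the tests of how the pools resemble each other were chosen only after the data were seen.

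T cell-like and NK cell-like cells with at least 10 CD8a tags (110) were set against those with at least 10 CD4 tags (296), on all UMIs summed per pool. Left out were 6 cells with both tags, and 1 CD8a-tagged and 3 CD4-tagged cells with more than 20 mesenchymal UMIs. The CD8a-tagged cells had more RNA of Cd8a, by a log2 fold change of 7.92 ± 0.39 (SE, n = 5 pools, edgeR adjusted p = 1.79e-12), and of Cd8b1, by 6.58 ± 0.30 (adjusted p = 1.13e-12). The cytotoxic genes Gzmb, at 3.93 ± 0.37 (adjusted p = 9.16e-08), Nkg7, at 3.47 ± 0.31, and Ccl5, at 3.41 ± 0.33, were higher, as were Plac8, at 4.28 ± 0.33, and Klre1, at 3.78 ± 0.49. Cd4, at -6.42 ± 0.50 (adjusted p = 9.08e-09), Maf, at -3.51 ± 0.39, and Lef1, at -1.20 ± 0.17, were lower. In all 289 of 2008 genes passed (118 higher, 171 lower), and 192 in DESeq2. The real split was the 1 with the most genes among 100, and the highest other split gave 32. The splits were not limited to those that part the 2 groups within each pool, so they cannot exclude chance. Most NK cell-like cells in the comparison carried CD8a tags, 64 against 19 with CD4 tags, so the genes also separate those classes. These genes were chosen after their values were seen.

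The pools resembled each other unevenly. Pools 2 and 4 were the most correlated pair in 6 of 10 classes. This pair was picked after it was seen, and the classes come from the same pools, so no chance value is given. Among these classes its correlation ran from -0.058 in fibroblast-like cells (next pair -0.066) to 0.478 in inflammatory macrophage-like cells (next pair 0.262). The T cell-like cells of pools 2 and 4 lay mainly in cluster 24 (30 and 43 cells, against 5 and 12 in cluster 4), and those of pools 1, 3 and 5 in cluster 4 (84, 107 and 46 cells, against 6, 4 and 0 in cluster 24). The mean deviation of NF-kB targets in pools 1 to 5 was 0.02, 0.68, -0.37, 0.61 and -0.93 on the log2 scale, and that of immediate early genes 0.61, 0.17, -0.07, 0.23 and -0.94. The labels give no batch for the pools.

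Cluster 28, part of the modulated smooth muscle-like class, held 16 cartilage-like cells led by Ibsp, Col2a1, Acan, Col10a1 and Chad. Of these, 7 carried a hashtag, all of pool 3. The unnamed cluster 15 made up 3.61% ± 3.36 of leukocytes (SD, n = 5 pools) and was led by Arg1, Il1rl1, Klrg1 and Gata3. The unnamed cluster 5, led by Serpinb2 and Ccr3, made up 2.27% ± 2.11 and had a median of 626 UMIs.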
